A study of Mus musculus with 3 samples.

How the data were processed

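Ribosomal RNA-depleted total RNA of the cytosolic fraction was sequenced from 3 libraries of bone marrow-derived macrophages of C57BL/6J mice, made from 1 µg of RNA with inserts of 250 to 400 nt, per the labels. The libraries are 3 separate biosamples that the labels number as biological replicates 1 to 3. All of them carry the same donor record, so the spread and the adjusted p-values given here measure variation between these samples only. All 3 form 1 group, and no sample was left out.

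Each library has a gene table and 2 transcript tables, made on the mm10 genome build with the GENCODE M21 annotation, per the README notes deposited with the samples. By those notes, the gene table and the first transcript table were made from transcriptome alignments, and the second transcript table directly from the FASTQ files. The programs are not given in the sources used here; the column sets are those that RSEM (gene table and first transcript table) and kallisto (second transcript table) write. The expected counts of the gene table and first transcript table, and the estimated counts of the second, are counts that the authors' programs assigned to each gene or transcript, with no normalization, per the file headers and the values, which are not whole numbers. The TPM values were computed by the authors with a correction for effective length and sum to the same total in each library, as deposited. The FPKM values in the deposited gene table are fragments per kilobase of effective length scaled to library size, per the file headers, and are proportional to TPM within a library. The percent values of the first transcript table are, per the file headers, the share of a gene's TPM that each transcript takes. The posterior SD of each count is deposited in the gene table in counts and comes from the authors' program. Whether strand was used in counting is not given in the sources used here.

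The gene table holds 81881 features, of which 55536 are annotated genes. Sequences of the phiX control (0.227, 0.110 and 0.0959% of counts in replicates 1, 2 and 3), 96 ERCC spike-in sequences (0 counts) and 26248 tRNA features (0, 1 and 0 counts) were left out of library sizes and tests, while the deposited TPM were used unchanged. The second transcript table gives 55450 genes when summed by gene, and lacks 95 of the 141862 annotated transcripts. Genes with any count numbered 17561, 18743 and 18558 in replicates 1, 2 and 3. For a gene with 0 counts the limit given is 3 counts in TPM.

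The gene lists, the comparisons, the rule for named genes and 74 alternatives were fixed before the data were examined. A further 9 alternatives, among them a rescaling of TPM over nuclear protein-coding genes and counts of the second transcript table, were chosen after seeing the data. A gene was called detected at 1 TPM or more in all 3 libraries. The 28 lists were inflammatory cytokines and chemokines, feedback inhibitors of TLR signalling, NF-kappaB subunits and IkappaB proteins, TLR4 receptor and proximal signalling, immediate early genes, interferon response genes, antimicrobial and acute phase genes, macrophage identity genes, alternative activation genes, antigen presentation and costimulation, inflammasome and pyroptosis, glycolysis, sterol and fatty acid synthesis, cell cycle, nuclear long noncoding RNAs, cytosolic housekeeping mRNAs, small structured noncoding RNAs, replication-dependent histones, mitochondrially encoded mRNAs, sex-linked genes, and markers of neutrophils, dendritic cells, T and NK cells, B and plasma cells, erythroid cells and megakaryocytes, mast cells and basophils, stromal and endothelial cells, and osteoclasts. The list of small RNAs has 10 members, of which Rn7sl1 and Rn7sl2 are not annotated under these symbols, so 7SL RNA was described by Rn7s1 and Rn7s2.

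Genes were named by a rule: in each list the 4 members with the highest mean TPM and up to 4 others that were lowest or not detected; the 15 most abundant genes, overall and among genes of 300 nt or more that are not mitochondrially encoded; every gene of the pairs and transcript shares; the 10 genes with the smallest adjusted p for variability at a mean of 5 TPM or more; and the 5 sex-linked genes. Other list members named for a level or for their variability, the chromosome 1 copies of mitochondrial genes, genes named for the difference between the transcript tables, and the long noncoding RNAs in the last part were chosen after their values were seen.

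The median of log2(TPM + 1) was taken over the members of a list in each library, for 4 differences between lists, and log2 ratios of TPM without a pseudocount were taken for 12 pairs of genes. List medians were also ranked among 10000 random lists of the same size, which describes these libraries and is not a p-value across replicates. Variability was tested in edgeR 4.0.16 (R 4.3.3) on rounded expected counts with TMM scaling, filterByExpr and estimateDisp. The residual deviance of each gene under the trended dispersion was set against a chi-square distribution with 2 degrees of freedom, adjusted by Benjamini-Hochberg over all genes tested at 0.05, and also over each list alone. DESeq2 1.42.0 gave the genes it marks as dispersion outliers as an alternative. The edgeR procedure was tested on simulated data of 12102 genes. It recovered 30% of 100 genes given 10 times the trended dispersion and 68% of 100 genes given 50 times, with 2 false calls, and made 0 calls when no gene was changed. The changed genes were drawn from those with a mean of at least 100 counts, and all others lay exactly on the fitted trend. The simulation therefore does not show recovery at lower counts, or false calls where genes scatter about the trend. TMM factors were 0.955, 1.03 and 1.02 in replicates 1, 2 and 3. The chi-square comparison of a pair of libraries used genes with a total of at least 20 counts. Shares of leading transcripts were computed for 22 genes in both transcript tables. For the comparison of those tables, a pseudocount of 1 TPM was used and genes over 2-fold apart in the same direction in all 3 libraries were counted.

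The alternatives covered the detection threshold, the pseudocount, other scalings, the second transcript table, other filters and tools for variability, and leaving out each replicate in turn. Matched-gene tests used the 100 detected genes nearest in length, GC content and level. Bootstrap SEs came from 2000 draws over the genes of a set, so they do not measure variation between replicates. Shared sequence was measured in words of 31 bases. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9 was used for all else.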

Results

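Total RNA-seq was analysed from the cytosolic fraction of macrophages grown from the bone marrow of C57BL/6J mice. The cells were exposed to 100 ng/ml Lipid A, the part of bacterial lipopolysaccharide that binds the receptor TLR4, for 12 h. They were then kept without it for 12 h and given 100 ng/ml again for 90 min before harvest. A second exposure of this kind is the layout used to study endotoxin tolerance, the altered response of macrophages to a repeated ligand. The 3 libraries form 1 group of 3 replicates, and cells left unexposed or exposed once were not analysed here, so the values below are levels in twice-exposed cells and not responses. The libraries held 40730514, 70484996 and 49726063 expected counts in replicates 1, 2 and 3. At this depth 1 TPM (the unit of length-corrected transcript abundance) of a 2 kb transcript corresponded to 109 to 209 counts. All levels below are mean TPM ± SD over the 3 libraries (n = 3) unless another unit is given.

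The most abundant RNA of the gene table was 7SL RNA, the RNA of the signal recognition particle that directs ribosomes to the endoplasmic reticulum. Its genes Rn7s1 (ENSMUSG00000099021.1, mm10 chromosome 12, 69159295 to 69159594) and Rn7s2 (ENSMUSG00000099250.1, chromosome 12, 69361182 to 69361481) together took 59.2 ± 2.35% of TPM (n = 3) but 7.94 ± 1.09% of counts, and stood at 127921 ± 20934 TPM each in the second transcript table. Protein-coding genes took 89.6 ± 1.72% of counts and 30.4 ± 2.60% of TPM, so a level rescaled over nuclear protein-coding genes alone is 3.33 ± 0.284 times the TPM given here. The mRNAs of the ferritin subunits Fth1 (17136 ± 1254) and Ftl1 (7303 ± 486), which store iron, were the most abundant mRNAs. They were followed by the chemokine Ccl5 (5268 ± 883), the actin-binding peptide gene Tmsb4x (4689.6 ± 593) and the acute phase gene Saa3 (4085 ± 2058).

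In all 3 libraries 9276 genes reached 1 TPM, of which 8838 were protein-coding, and 3769, 445 and 23 genes reached 10, 100 and 1000 TPM. The next most abundant mRNAs were B2m (3742 ± 536) and H2-K1 (2391 ± 58.7) of the class I antigen-presenting complex, Actb (3496 ± 535), and the lysosomal genes Psap (3422 ± 209.8), Lyz2 (3262 ± 426) and Ctsd (2650.3 ± 209). The noncoding RNAs among the 15 most abundant genes were Rn7s1, Rn7s2, Rn7sk (45139 ± 28274), Rpph1 (33864 ± 12159) and Rmrp, which the annotation holds under 2 overlapping gene entries (8367 ± 3456 and 4241 ± 1113) that are uncertain because reads can be shared between them. Reads of the near-identical Rn7s1 and Rn7s2 can likewise be shared, and the posterior SD of their counts given in the files was at most 1.89% of the count. Genes annotated as ribozymes, Rpph1 and Rmrp among them, took 4.22 ± 1.52% of TPM but 0.641 ± 0.283% of counts. The levels of these short RNAs therefore rest strongly on the length correction of TPM.

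The first comparison set the genes that a TLR4 ligand is known to switch on against a fixed list of genes taken as feedback inhibitors of the same pathway. Of the 24 annotated inflammatory cytokines and chemokines, 18 were detected at 1 TPM or more in every library, with a list median of 16.9 TPM (4.16 on the log2 scale with a pseudocount of 1, and 6.60 over detected members alone), and the levels spanned several orders of magnitude. Highest were the chemokines Ccl5, Ccl4 (946 ± 568) and Ccl3 (882 ± 463), which attract leukocytes, and the cytokine Tnf (815 ± 262; ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007). The interleukins Il1a (306 ± 95.2) and Il1b (281 ± 112) were also abundant, whereas Il6 (17.1 ± 11.4), Il12b (14.5 ± 7.76) and the nitric oxide synthase Nos2 (6.92 ± 4.74) were far lower. Il23a (0.240 ± 0.178), Csf3 (0.227 ± 0.140), Il12a (0.170 ± 0.0624) and Lif (0.05 ± 0.02) stayed under 1 TPM in every library, and Csf2 (1.60 ± 1.06) and Cxcl3 (1.22 ± 0.767) passed it in only some libraries. Of the 26 feedback inhibitors, 24 were detected, with a median of 33.1 TPM. They were led by Nfkbia (383 ± 91.4), which holds NF-kappaB in the cytoplasm, the ubiquitin-editing enzyme Tnfaip3 (191 ± 79.3), Nfkbiz (177 ± 53.5) and the mRNA-destabilising protein Zfp36 (152 ± 72.1). Membership was fixed beforehand and the function of members was not tested, so a member such as Nfkbiz need not act only as an inhibitor. Cish (0.867 ± 0.471) and Sigirr (0.460 ± 0.0624) missed the threshold in at least 1 library, and the anti-inflammatory cytokine Il10 stood at 5.47 ± 2.68. Per library, the median of log2(TPM + 1) of the cytokines lay below that of the inhibitors by a difference of -0.96 ± 0.63 (n = 3), negative in all 3 libraries (-0.43, -0.80 and -1.66). The order depended on the undetected members, because over detected members alone the difference was 1.24. With 3 libraries the exact sign-flip test cannot go below p = 0.25 two-sided, so no p is given for this or the later list differences.

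**Figure D1:**
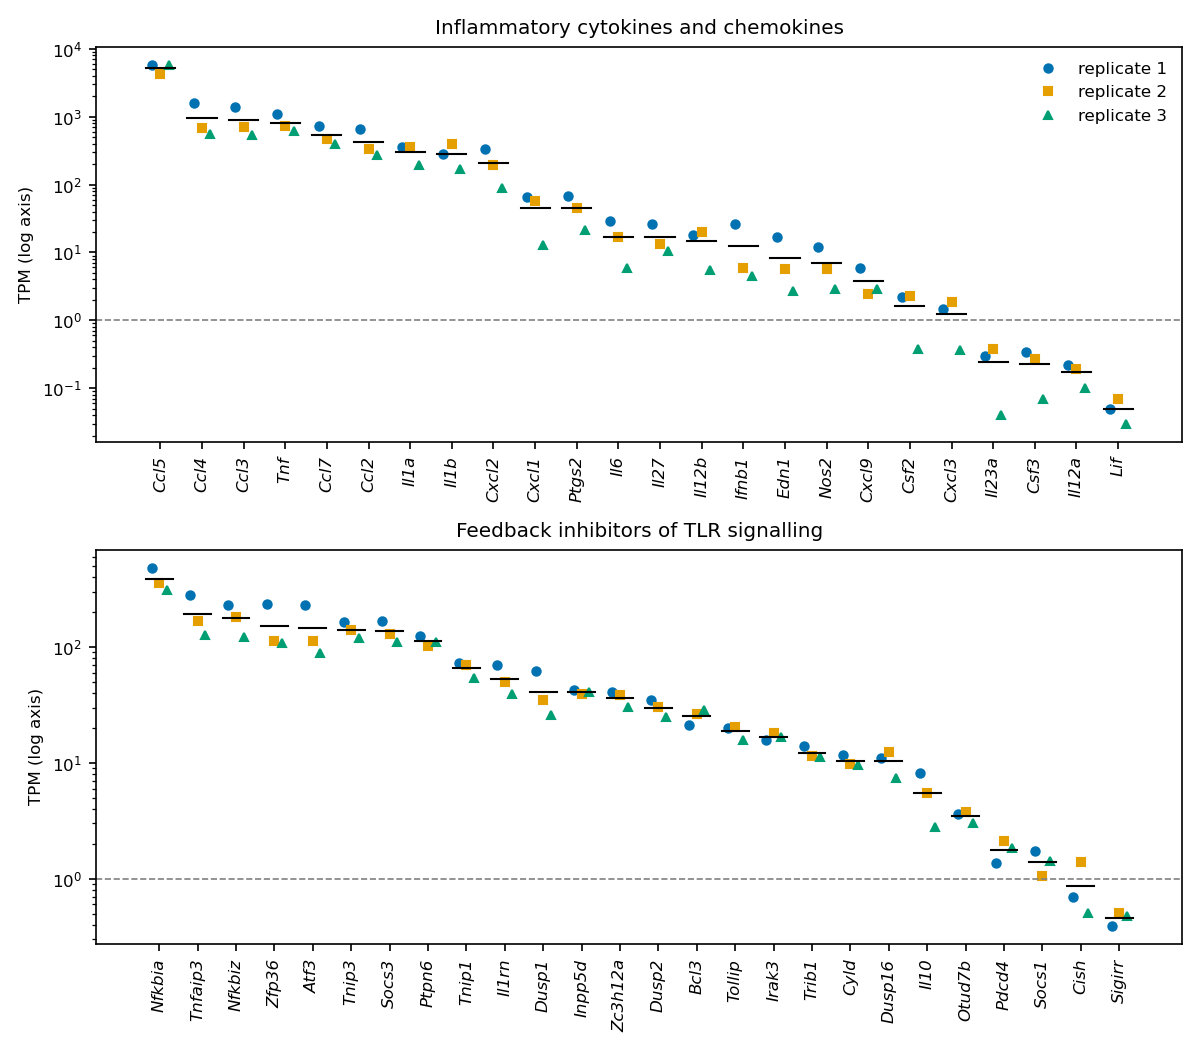
TPM on a log axis of each of the 24 inflammatory cytokine and chemokine genes (top) and the 26 feedback inhibitor genes (bottom), with a symbol per replicate, a bar at the mean of the 3 libraries and a dashed line at 1 TPM. Ccl5 lies at 5268 TPM and Lif at 0.05 TPM, while the inhibitors lie between 0.460 and 383 TPM.

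Ratios within each library gave the balance of single pairs. The interleukin receptor antagonist Il1rn (53.4 ± 15.7), which blocks the receptor of Il1b, was lower than Il1b in every library, with a log2 ratio of -2.35 ± 0.54 (n = 3). Il10 relative to Il12b gave -1.33 ± 0.44, and Il12b exceeded Il12a, with which it forms a cytokine dimer, by 6.29 ± 0.46 (3.56 with a pseudocount of 1 TPM on both genes). Tnf exceeded Il6 by 5.80 ± 0.78, and Ccl3 relative to Ccl5 gave -2.69 ± 0.71. Acod1 (1099.8 ± 324), whose product makes itaconate, exceeded Nos2 by 7.51 ± 0.60. Nfkbia exceeded the related inhibitor Nfkbie by 2.74 ± 0.19, and the inhibitory kinase family member Irak3 exceeded Irak1 by 0.55 ± 0.13. The costimulatory receptor gene Cd80 (6.41 ± 1.27) was lower than Cd86 (22.7 ± 5.03), with a log2 ratio of -1.82 ± 0.16. Arg1 had 0, 2 and 1 counts in replicates 1, 2 and 3, so its log2 ratio to Nos2 had no finite mean, and it was -9.15 and -5.86 in replicates 2 and 3. Each of the ratios with a mean kept its sign in all 3 libraries.

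Transcripts of the receptor pathway itself were present at moderate levels. Of 25 members of the TLR4 receptor and proximal signalling list, 24 were detected, with a median of 13.0 TPM. Cd14 (236 ± 104), the coreceptor that hands lipopolysaccharide to TLR4, was highest, ahead of the adaptor Myd88 (58.0 ± 6.86), the kinase Irak2 (40.7 ± 6.88) and Tbk1 (30.9 ± 4.54). Tlr4 itself stood at 20.7 ± 4.87 and its partner Ly96 at 26.2 ± 2.43, and the lowest were Tirap (2.27 ± 0.255), Tab1 (1.72 ± 0.202) and Lbp (0.650 ± 0.104), the last not detected. All 11 NF-kappaB subunits and IkappaB proteins were detected (median 42.3 TPM), from Nfkbia down to Nfkbid (7.03 ± 1.81), with the subunits Nfkb2 (43.5 ± 6.07), Nfkb1 (42.3 ± 7.0), Rel (36.2 ± 10.3), Rela (31.8 ± 5.95) and Relb (27.3 ± 4.38) close together. Among 22 immediate early genes, which are transcribed within minutes of a stimulus, 18 were detected (median 30.1 TPM). Klf6 (233 ± 74.3), Gadd45b (155 ± 42.1), Zfp36 and Atf3 (145 ± 76.0) were highest. Fos (7.48 ± 1.11) was low, and Fosb (0.577 ± 0.690), Fosl1 (0.0167 ± 0.0153), Klf4 (0.957 ± 0.599) and Nr4a1 (1.76 ± 1.68) did not reach 1 TPM in every library.

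Interferon response genes are switched on by type I interferon, which is made downstream of TLR4. All 32 were detected, 31 of them at 10 TPM or more, and the list median was 176 TPM. The chemokine Cxcl10 (1080.5 ± 716; ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), the antiviral enzyme Rsad2 (914 ± 481), Ifit2 (838 ± 292) and the transcription factor Irf7 (712 ± 172) were highest, and Irf9 (26.5 ± 2.72), Mx2 (19.4 ± 4.04), Oas2 (13.7 ± 2.95) and Cxcl11 (7.27 ± 7.25) lowest. The interferon gene Ifnb1 itself stood at 12.3 ± 12.3, with 26.5, 5.81 and 4.54 TPM in replicates 1, 2 and 3. Per library the interferon response median exceeded the cytokine median by 3.24 ± 0.67 on the log2 scale (n = 3), higher in 3 of 3 libraries. Over detected members alone the difference was 0.90. Cxcl10 exceeded Cxcl9 (3.76 ± 1.84) by a log2 ratio of 8.08 ± 0.27 (6.51 on expected counts, which are not corrected for length).

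Genes of antimicrobial defence and of antigen presentation were detected almost throughout. Of 22 antimicrobial and acute phase genes 18 were detected (median 65.6 TPM), led by Saa3, Lyz2, the protease Ctsb (2109 ± 250.1) and Acod1, while Slpi (1.13 ± 0.541), Lyz1 (1.09 ± 0.272), Camp (0.193 ± 0.0252) and Ptx3 (0.0267 ± 0.0153) were lowest. Lyz1 and Lyz2 are related genes, so Lyz1 is uncertain at this level. All 20 antigen presentation and costimulation genes were detected (median 63.6 TPM). The class I genes B2m, H2-K1 and H2-D1 (1686 ± 72.4) stood far above the class II genes H2-Aa (68.1 ± 10.5) and H2-Ab1 (48.8 ± 5.93) and their regulator Ciita (2.27 ± 0.653). All 14 inflammasome and pyroptosis genes were detected (median 30.3 TPM), with Il1b, Ninj1 (168 ± 12.6), which ruptures the membrane of dying cells, the sensor Nlrp3 (94.1 ± 25.5) and Casp1 (87.6 ± 13.2) highest and Nlrp1b (1.20 ± 0.115) lowest.

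Transcripts that mark macrophages were set against those of alternative activation, the state that interleukin 4 induces. All 22 macrophage identity genes were detected (median 232 TPM), with Lyz2, Ctsd, Ctss (1351 ± 193) and the receptor chain Fcer1g (1306 ± 95.6) highest, Adgre1 (652 ± 113), Cd68 (642 ± 93.1) and Csf1r (146 ± 12.2) in between, and Cebpa (7.13 ± 1.5) lowest. Of 15 alternative activation genes 7 were detected (median 0.257 TPM): Tgm2 (55.1 ± 18.3), Il4ra (33.6 ± 8.04), Clec7a (28.2 ± 5.0), Mrc1 (24.0 ± 6.02), Ccl22 (4.41 ± 0.877), Clec10a (2.85 ± 0.361) and Chil3 (2.71 ± 0.841). Retnla and Ccl17 had 0 counts in every library, which allows up to 0.135 and 0.177 TPM. Such limits rest on 3 counts in the library where that is worth most, and they cover counting error only. Per library the macrophage median exceeded the alternative activation median by 7.52 ± 0.18 on the log2 scale (n = 3), in 3 of 3 libraries, and by 3.31 over detected members alone.

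Markers of other cells that a bone marrow culture could hold were mostly under 1 TPM. Of 12 neutrophil markers 3 were detected, S100a9 (6.58 ± 1.26), S100a8 (4.12 ± 1.39) and Mmp8 (2.15 ± 0.313), while Mpo (0.0633 ± 0.0306) and Elane (0.0367 ± 0.0252) were near 0 and Ly6g and Retnlg had 0 counts (limits 0.120 and 0.137 TPM). Of 10 dendritic cell markers 3 were detected, Cst3 (210.2 ± 51.0), which macrophages also express, Ccr7 (1.45 ± 0.169) and Batf3 (1.23 ± 0.0400), and Flt3 stood at 0.04 ± 0.01. Of 12 T and NK cell markers 2 were detected, Cd4 (16.4 ± 3.71) and Il7r (6.02 ± 3.31), while Cd3e stood at 0.0300 ± 0.0436 and Cd3g had 0 counts (limit 0.0443 TPM). Cd79b (1.31 ± 0.361) was the 1 of 8 B cell and plasma cell markers detected, Pf4 (90.6 ± 20.1) the 1 of 10 erythroid and megakaryocyte markers, and the endothelial receptor Kdr (4.93 ± 3.28) the 1 of 10 stromal and endothelial markers. None of 6 mast cell and basophil markers was detected, the highest being Gata2 (0.05 ± 0.052). Of 8 osteoclast markers 3 were detected, Acp5 (10.7 ± 1.62), Nfatc1 (7.87 ± 0.129) and Atp6v0d2 (4.69 ± 1.36). None of 5 sex-linked genes was detected in all libraries: Xist stood at 0.777 ± 0.363, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every library (limits 0.0138 to 0.0466 TPM). Xist overlaps its antisense gene Tsix, and the sources used here do not say whether strand was used in counting, so its level is uncertain.

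Against 10000 random lists of the same size drawn from genes detected in at least 1 library, the list medians of inflammatory (percentile 99), TLR4 signalling (94.6) and sterol synthesis genes (93.3) were lower in rank than those of interferon response and macrophage identity genes (100 each). Histones (0.14) and alternative activation, cell cycle and nuclear long noncoding RNA genes (0 each) ranked lowest among the lists that are not cell type markers or sex-linked genes. Undetected members stayed in these medians while the random lists held only genes detected in some library, so low ranks partly follow from that choice. Against random lists of all annotated genes, the same lists ranked at 99.9, 99.5, 99.99 and 99.3 in the order given. All 19 glycolysis genes were detected (median 53.9 TPM), led by Gapdh (334 ± 35.5), Aldoa (165 ± 16.9), Pkm (150.2 ± 13.0) and Ldha (106 ± 10.4), with Pfkm (1.61 ± 0.118) lowest. All 21 sterol and fatty acid synthesis genes were detected (median 13.0 TPM), with the cholesterol exporters Abca1 (85.4 ± 10.2) and Abcg1 (64.1 ± 8.41) and the desaturase Scd2 (61.8 ± 15.8) highest and Lss (2.54 ± 0.345) lowest. Of 20 cell cycle genes 9 were detected (median 1.24 TPM). The highest of them was Cdkn1a (216 ± 61.2), an inhibitor of cyclin-dependent kinases, followed by the replication factor Pcna (66.0 ± 9.61) and Mki67 (17.3 ± 5.25), while the mitotic genes Plk1 (0.193 ± 0.0737), Cdc20 (0.210 ± 0.0900), Ccnb2 (0.243 ± 0.225) and Bub1 (0.390 ± 0.0985) were not detected. Detected cell cycle members numbered 17 on the protein-coding scale and 4 at a threshold of 5 TPM, so this count is set by the threshold. Of 15 replication-dependent histone genes 9 were detected (median 2.08 TPM), with Hist1h2bc (53.3 ± 3.34) and Hist1h1c (22.8 ± 2.10) highest. Histone genes share near-identical sequences, so single members are uncertain.

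**Figure D2:**
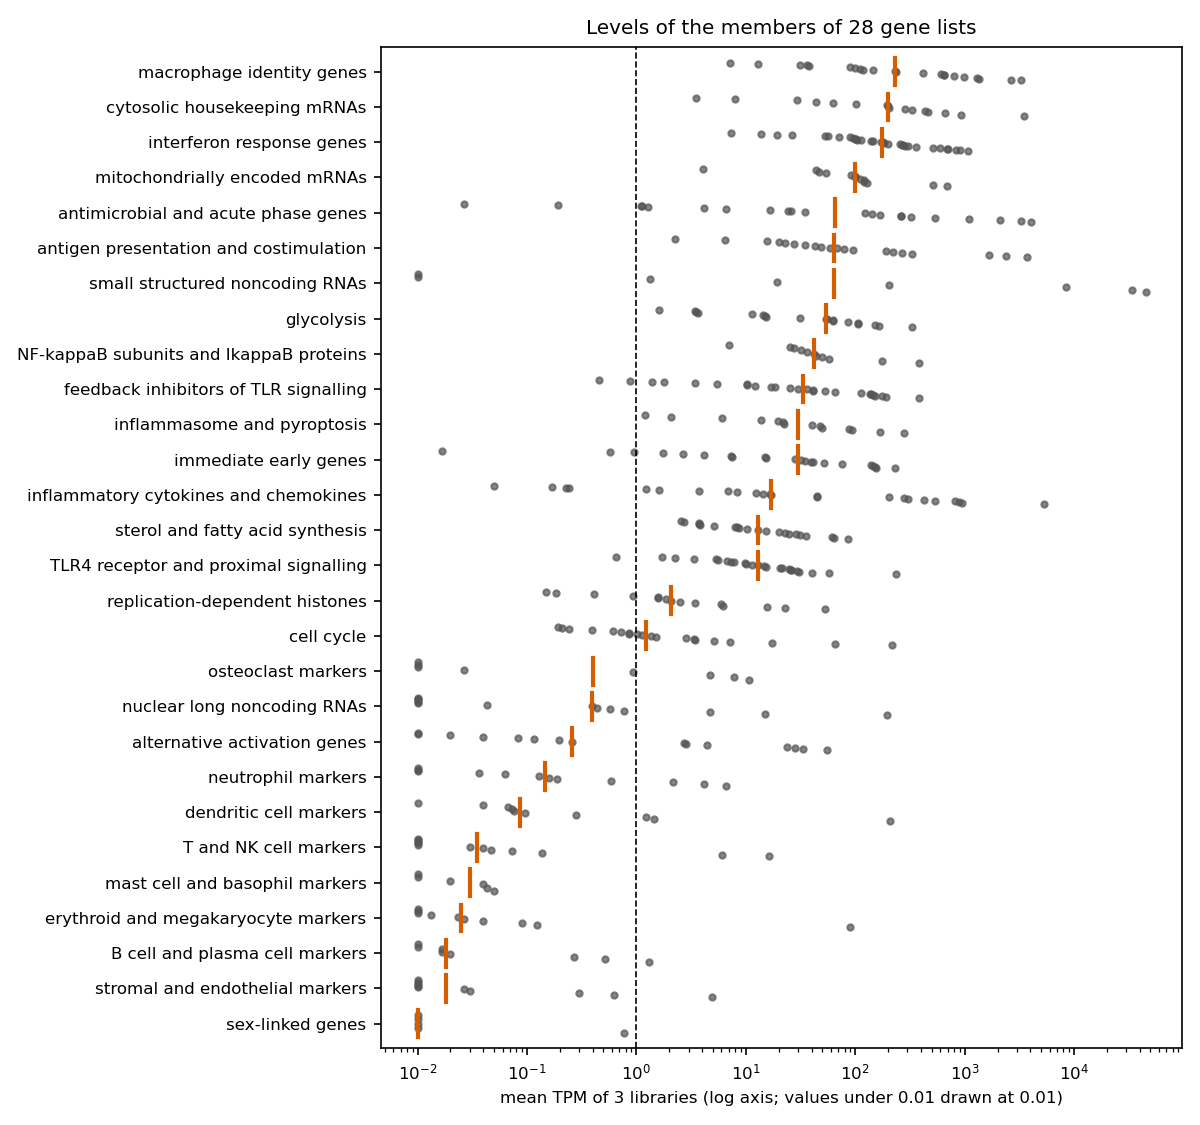
Mean TPM over the 3 libraries of every annotated member of the 28 gene lists, on a log axis with values under 0.01 drawn at 0.01; each point is a gene, the orange bar is the list median and the dashed line is 1 TPM. Macrophage identity genes have a median of 232 TPM and interferon response genes of 176 TPM, whereas the markers of other cell types have medians under 1 TPM.

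The fraction was described by RNAs whose place in the cell is known. All 16 cytosolic housekeeping mRNAs were detected (median 199.9 TPM), from Actb and the elongation factor Eef1a1 (931 ± 134) to Tbp (3.52 ± 0.430). Of 13 nuclear long noncoding RNAs 3 were detected (median 0.397 TPM): Malat1 (194 ± 132), a nuclear speckle RNA, Neat1 (14.8 ± 7.51), the scaffold of paraspeckles, and Dleu2 (4.71 ± 0.544). Tsix, Rian and Miat had 0 counts in every library (limits 0.0135, 0.0391 and 0.0154 TPM). Per library the housekeeping median exceeded the nuclear median by 7.18 ± 0.26 on the log2 scale (n = 3), in 3 of 3 libraries, and by 3.76 over detected members alone. Malat1 relative to Actb gave -4.37 ± 0.97. Of the 13 nuclear RNAs 9 were under 1 TPM in every library, and no nuclear or whole-cell RNA was analysed here. Low expression and fractionation therefore cannot be told apart, and these differences do not measure the purity of the fraction. Of 8 annotated small structured noncoding RNAs 5 were detected, namely Rn7sk, Rpph1 and Rmrp, which act in the nucleus or in RNA processing, Vaultrc5 (203 ± 47.3) and Scarna2 (19.3 ± 8.51), while Rny1 and Rny3 were listed at 0 (5.64 and 17.7 TPM in the second transcript table, which detected 7 of the 8). Their list median was 63.5 TPM (6.01 on the log2 scale, 13.03 over detected members alone). Rn7sk was at 21186, 37904 and 76327 TPM and Malat1 at 103, 132 and 345 TPM in replicates 1, 2 and 3.

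**Figure D3:**
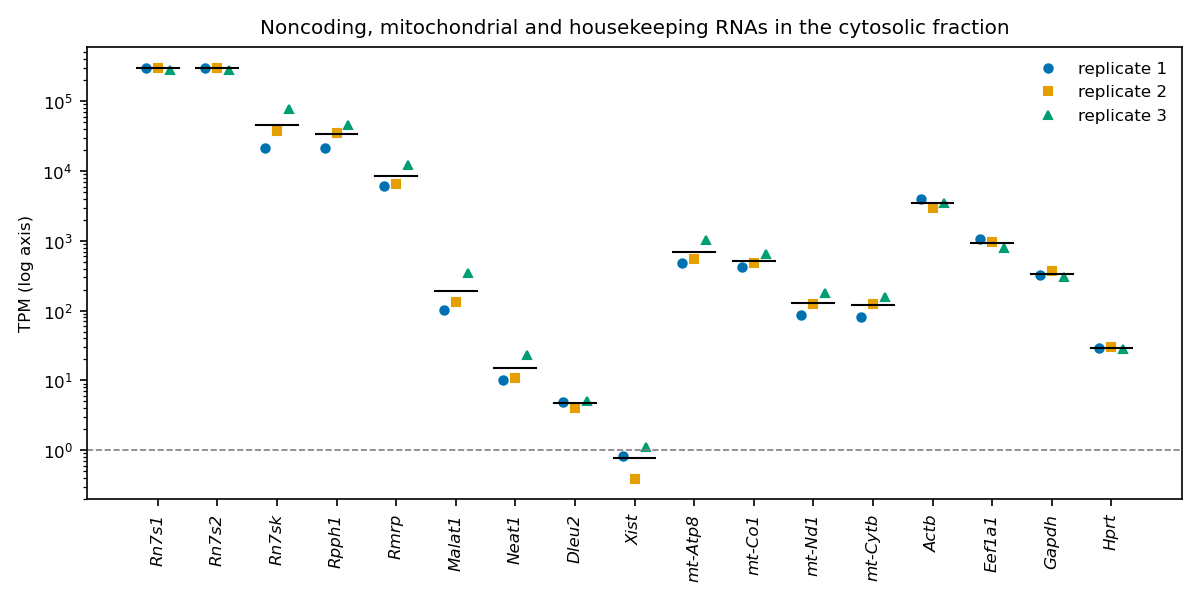
TPM on a log axis of noncoding, mitochondrially encoded and housekeeping RNAs, with a symbol per replicate, a bar at the mean of the 3 libraries and a dashed line at 1 TPM. Rn7sk, Rpph1, Rmrp, Malat1, Neat1 and the mitochondrially encoded genes shown are highest in replicate 3, while Hprt lies at 29.2 ± 1.18 TPM (n = 3).

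Mitochondrially encoded mRNAs took 0.227 ± 0.0772% of counts (n = 3). Of the 13 genes 12 were detected (median 99.5 TPM), with mt-Atp8 (690.1 ± 301) and mt-Co1 (519 ± 118) highest in the gene table. In the second transcript table mt-Atp8 stood at 156 TPM and mt-Co1 at 292 TPM, so the level of mt-Atp8 is uncertain. mt-Co2 stood at 6.88, 0 and 5.30 TPM in replicates 1, 2 and 3. Of the 31-base words of mt-Co2, 99.5% also occur in annotated transcripts of chromosome 1, where the pseudogene Gm28661 (24614885 to 24615565) was listed at 437 ± 117. mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l share 98.1% or more of their words with such transcripts, mt-Nd4 shares 62.8% and mt-Co1 29.6%, so the levels of these genes are uncertain. mt-Nd1 (129 ± 46.6), mt-Cytb (121 ± 39.6), mt-Nd5 (98.8 ± 27.8) and mt-Nd2 (54.0 ± 18) share none with chromosome 1. With annotated transcripts of other chromosomes mt-Nd1 shares 0%, mt-Cytb 6.55%, mt-Nd2 13.5%, mt-Nd5 16.8%, mt-Co1 47.1% and mt-Co2 47.1% of words.

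The only variation the design holds is between replicates. Of the 20 inflammatory cytokines and chemokines tested, 15 varied more than the edgeR dispersion trend (16 adjusted over the list alone). These included Edn1 (adjusted p = 2.6e-15, edgeR, 6.21-fold between the highest and lowest library), Ifnb1 (adjusted p = 3.7e-12, 5.84-fold), Cxcl1 (adjusted p = 7.7e-12, 4.98-fold) and Il6 (adjusted p = 1.2e-09, 4.89-fold). Of the 15, 12 were highest in replicate 1 and 14 lowest in replicate 3. The count was 10, 10 and 4 without replicate 1, 2 and 3, and DESeq2 marked 8. Ccl5 and Tnf were among those that did not pass (adjusted p = 1.00 and 0.956, edgeR). Among 21 immediate early genes tested 7 passed (11 adjusted over the list alone; 3, 4 and 2 without replicate 1, 2 and 3; 3 in DESeq2), including Egr2, Nr4a1 and Atf3. Among 32 interferon response genes 3 passed (5 adjusted over the list alone; 0, 1 and 3 without replicate 1, 2 and 3; 3 in DESeq2), namely Cxcl11, Cmpk2 and Cxcl10.

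Of 26 feedback inhibitors 3 passed (6 adjusted over the list alone; 1, 2 and 0 without replicate 1, 2 and 3; 0 in DESeq2), namely Atf3, Dusp1 and Il10, and of 20 antimicrobial genes 3 (3 adjusted over the list alone; 1 without each replicate in turn; 2 in DESeq2), Lcn2, Marco and Saa3. Saa3 was at 3676, 2261 and 6316 TPM in replicates 1, 2 and 3. Malat1, Neat1 and Xist passed among 8 nuclear long noncoding RNAs tested (3, and 4 adjusted over the list alone, with 4, 3 and 0 without replicate 1, 2 and 3 and 2 in DESeq2), each highest in replicate 3. Rn7sk and Rmrp passed among 5 small structured RNAs (2, and 4 adjusted over the list alone, with 0, 1 and 0 without replicate 1, 2 and 3 and 1 in DESeq2). Of 12 mitochondrially encoded mRNAs 6 passed (10 adjusted over the list alone, with 0, 4 and 1 without replicate 1, 2 and 3 and 1 in DESeq2), each lowest in replicate 1. Single genes passed in the lists of macrophage identity (Cebpb), antigen presentation (Cd40), sterol synthesis (Scd1), T and NK cell markers (Il7r), stromal markers (Kdr) and sex-linked genes (Xist), 1 in each also when adjusted over the list alone. DESeq2 marked Cebpb, Kdr and Xist, and not Cd40, Scd1 or Il7r. Without replicate 1, 2 and 3 these counts were 0, 0 and 1 for macrophage identity, 1, 0 and 0 for antigen presentation and for sterol synthesis, 1, 1 and 0 for T and NK cell markers and for sex-linked genes, and 0, 1 and 1 for stromal markers.

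No member passed in edgeR among 11 NF-kappaB genes, 25 TLR4 signalling genes, 14 inflammasome genes, 19 glycolysis genes, 16 housekeeping mRNAs, 19 cell cycle genes, 15 histone genes and 10 alternative activation genes tested, and DESeq2 marked none of them. Adjusted over the list alone, 1 TLR4 signalling gene and 1 inflammasome gene passed, and at an unadjusted p under 0.05 the counts in the order given were 1, 1, 1, 1, 0, 2, 2 and 2. Without replicate 1, 1 gene passed in each of the TLR4 signalling and inflammasome lists. Of the tested markers of neutrophils (5), dendritic cells (6), B cells (2), megakaryocytes (1) and osteoclasts (4) none passed in edgeR or DESeq2, with unadjusted counts of 0 except for 2 osteoclast markers, and 1 osteoclast marker passed when adjusted over the list alone.

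Over the 12256 genes tested, 240 varied more than the trend at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg; 843 at an unadjusted p under 0.05), against a common biological coefficient of variation of 16.3% (jackknife SE 2.23). Of the 240, 143 were highest in replicate 1, 57 in replicate 2 and 40 in replicate 3. The count was 119, 102 and 82 without replicate 1, 2 and 3, and the DESeq2 fit marked 59 genes, all among the 240. The smallest adjusted p among genes with a mean of 5 TPM or more belonged to Gm49369 (adjusted p = 3.3e-32, edgeR), a gene at 20.9, 390.3 and 498 TPM that overlaps Ctsd on the same strand of chromosome 7 and is therefore uncertain. Gm20721 (adjusted p = 8.9e-28, edgeR) and the ribosomal RNA gene CT010467.1 (adjusted p = 1.4e-23, edgeR), which overlaps Gm42418, are uncertain as well. The others of the first 10 were Cxcl11 (adjusted p = 4.1e-18, edgeR), Edn1, the endothelial lipase Lipg (4.5e-14), the interferon-inducible GTPase Tgtp1 (1.2e-12), Ifnb1, Cxcl1 and mt-Co3, the last also uncertain.

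By list, the detected interferon response genes were highest in replicate 1 in 32 of 32 cases on the TPM scale and with TMM-scaled CPM (counts scaled to library size). Their share highest in replicate 1 was 96.7% of 30 genes on the protein-coding scale and 93.8% in the second transcript table. Median deviations from the 3-library mean, relative to all detected genes, were 0.37, -0.27 and -0.10 on the log2 scale in replicates 1, 2 and 3 with TMM-scaled CPM. For the inflammatory cytokines and chemokines they were 0.69, -0.14 and -0.56, and for immediate early genes 0.36, -0.04 and -0.28. Deviations were highest in replicate 3 for small structured noncoding RNAs (-0.60, 0.03 and 0.62), mitochondrially encoded mRNAs (-0.55, -0.06 and 0.53) and nuclear long noncoding RNAs (-0.39, -0.40 and 0.78), and by less for markers of neutrophils (0.21 in replicate 3), dendritic cells (0.06) and osteoclasts (0.07), with 3 detected genes each. Macrophage identity genes (0.05, -0.05 and -0.03) and housekeeping mRNAs (0.04, 0.02 and -0.08) differed little. In the second transcript table the median of all detected genes itself lay at 0.11 in replicate 2, and relative to it the interferon response genes lay at 0.35, -0.23 and -0.12.

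**Figure D4:**
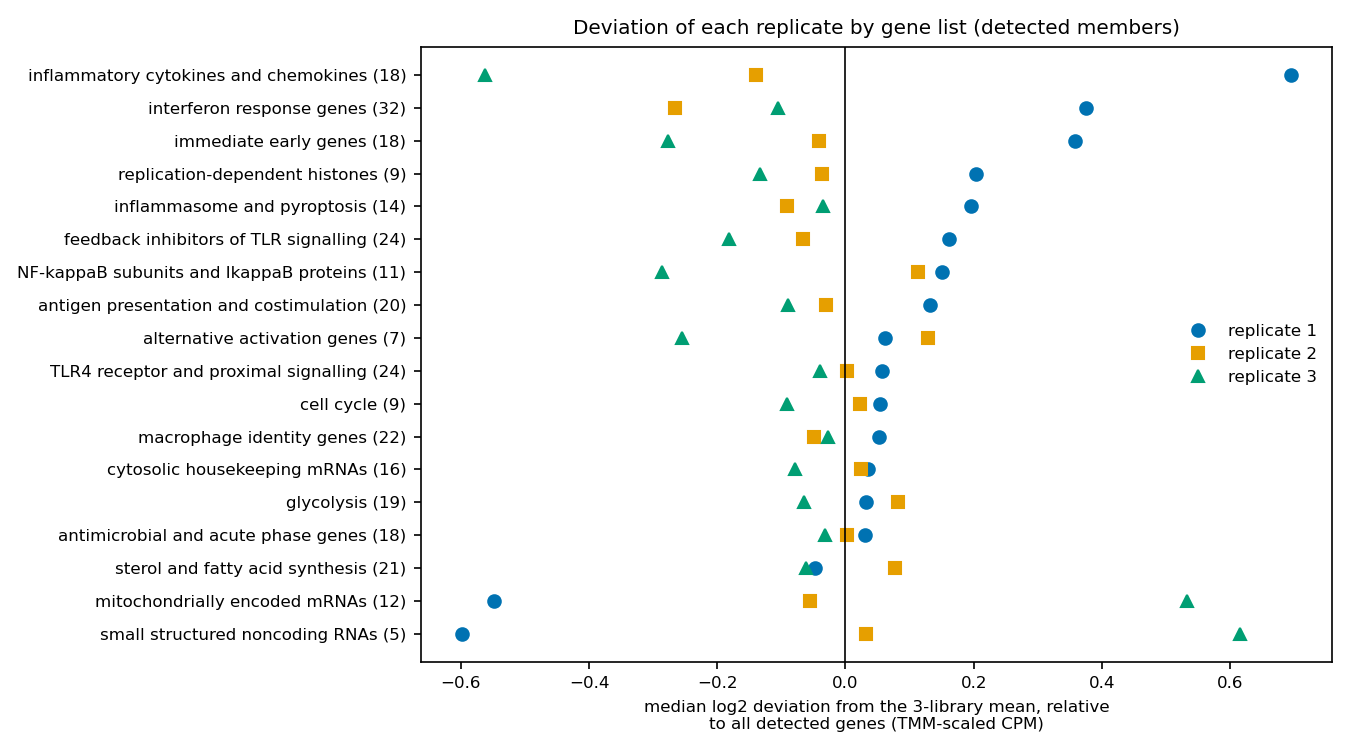
Median log2 deviation of each replicate from the 3-library mean, relative to all detected genes, for the detected members of each list with 5 or more of them (numbers in brackets), in TMM-scaled CPM. The inflammatory list lies at 0.69 in replicate 1 and -0.56 in replicate 3, while small structured noncoding RNAs lie at -0.60 and 0.62.

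The replicates were otherwise close. Across the 9276 detected genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.986 between replicates 1 and 2, 0.984 between 1 and 3 and 0.988 between 2 and 3 (Spearman's rho 0.982, 0.980 and 0.985). A chi-square comparison of the counts of each pair gave 118, 132 and 85.6 per degree of freedom; this compares libraries with counting error only.

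Genes of the pathway differed in how far 1 transcript carried the signal. Il10, Acod1 and Ifit3 have 1 annotated transcript each, and the leading transcript took a mean of 99.7% of the gene's TPM for Il1b and Nfkbia and 99.8% for Myd88, and more for Tnf and Ptgs2. Il1rn-201 took 76.6 ± 1.68% (n = 3) of Il1rn, Cd14-201 took 88.9 ± 1.55% of Cd14 and Neat1-202 took 90.8 ± 2.03% of Neat1. Signal was spread over several transcripts for Nfkb1 (Nfkb1-206, 47.1 ± 3.36%), Irak1 (Irak1-206, 49.3 ± 1.63%), Il15 (Il15-202, 42.5 ± 2.25%), Tnip1 (Tnip1-205, 54.9 ± 2.35%) and Irf7 (Irf7-201, 49.4 ± 0.156%). In the second transcript table Irf7-201 took 64.7% and Irak1-206 took 38.8%. The leading transcript of Sod2, Sod2-207 (53.2 ± 0.620%), is annotated as a processed transcript rather than a coding one. For Malat1 the leading transcript was Malat1-201 (42.5 ± 5.52%) in the first transcript table and Malat1-203 (44.8 ± 5.19%) in the second. Nfkbiz-204 (78.9 ± 3.88%), Tnfaip3-201 (78.1 ± 2.75%) and Irak2-201 (78.5 ± 6.00%) led their genes. Among 3756 genes with a mean of 10 TPM or more and at least 2 annotated transcripts, 3514 (93.6%) had the same leading transcript in every library, and 3156 (84.0%) had it in every library and both tables.

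The second transcript table, made from the same reads by another route, gave other levels to short RNAs and to some longer genes. It listed the pseudogenes Gm12896 and Gm12895 at 125082 ± 32156 and 125042 ± 32089 TPM (n = 3) and the microRNA genes Gm23935, Gm24245 and Gm24270 at 91909.6 ± 11869.5 TPM each, where the first table listed all of them at 0. Fth1 stood at 9094 ± 105 and Ccl5 at 2829.8 ± 279 TPM there. Levels of detected genes in the second table were a median log2 of -0.69 ± 0.08 (n = 3) from the first. Of 55450 genes, 357 were over 2-fold apart in the same direction in all 3 libraries, 124 higher and 233 lower in the second. Without genes under 300 nt or mitochondrially encoded genes, 247 of 46526 were over 2-fold apart, 64 higher and 183 lower. With both tables rescaled over protein-coding genes the median was -0.01 ± 0.01, and 107 of 21938 genes were over 2-fold apart, 74 higher and 33 lower. Both tables come from the same reads, so no test of their difference was made.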

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

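The tests of the length correction, of short RNAs kept and of the scaling of the libraries were chosen only after the result was seen. The phiX control sequences, which belong to no comparison, held 92657, 77423 and 47673 counts in replicates 1, 2 and 3, above the limit of 3 counts that 0 allows.

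Of 39 detected nuclear RNAs (small nuclear and Cajal body RNAs, Rn7sk, Rpph1 and the listed long noncoding RNAs), 32 were highest in replicate 3 with TMM-scaled CPM, among them Malat1, Neat1 and Rn7sk. Whether more short RNAs were kept in that library was checked on 12 short RNAs outside the nuclear set, 7SL RNA among them. Their median deviation there was -0.0033 (log2, bootstrap SE 0.05) against 0.39 (bootstrap SE 0.11) for the nuclear RNAs. Some of these 12 are annotated as long noncoding, antisense or sense intronic RNAs, and nothing here shows that they are not nuclear. The 12 were also not matched to the nuclear RNAs in length, so this comparison cannot decide the question. The 0.39 of the nuclear RNAs is without a length correction, which argues against the correction in TPM as the whole cause. With that correction the median was 0.63. Both medians used a pseudocount of 1, and small nuclear RNAs took 0.430% of TPM but 0.00619% of counts. The pseudocount therefore shrank their deviations more in CPM, and the gap between the 2 medians does not measure the correction. Nuclear RNA carried over into this fraction is a candidate explanation: the retained-intron share was highest in replicate 3 in 54.3% of 2476 genes (95% interval 52.3 to 56.3, chance 33.3). That interval treats the genes as independent, while genes of 1 library can shift together, so it does not measure variation between replicates. The summed share was 4.55, 5.29 and 4.91% in replicates 1, 2 and 3 and so was not highest in replicate 3. Mitochondrially encoded mRNAs, which are not nuclear, lay at 0.53 in replicate 3 with 75% of members highest there, which nuclear carry-over alone does not account for, and no biological explanation was tested, since there is 1 group.

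Of 50 detected inflammatory cytokine, chemokine and interferon response genes, 46 were highest in replicate 1, among them Ifnb1, Cxcl10 and Il6. Scaling of the libraries as the whole cause is argued against, because the median deviation in replicate 1 was 0.52 with TPM, 0.45 with TMM-scaled CPM, 0.43 in the second transcript table and 0.38 (bootstrap SE 0.04, 48 genes) with TPM rescaled over protein-coding genes. Gene length, GC content and level are argued against in the same way, because subtracting matched genes left 0.35 (bootstrap SE 0.05) of 0.45. These bootstrap SEs are over genes, treat them as independent and do not measure variation between samples. What else differed between the samples, such as the timing or strength of the second exposure, was not tested, and no biological explanation was tested, since there is 1 group.

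mt-Co2, at 6.88, 0 and 5.30 TPM in replicates 1, 2 and 3, was the lowest of the mitochondrially encoded mRNAs in each library. Reads assigned to nuclear copies are a candidate explanation, since 99.5% of the 31-base words of mt-Co2 occur in annotated chromosome 1 transcripts, of which Gm28661 was listed at 437 ± 117 TPM (n = 3). The share with chromosome 1 alone does not set mt-Co2 apart. mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l share 98.1% or more of their words with it and stood at 43.6, 91.2, 47.0 and 110 TPM. With annotated transcripts of other chromosomes mt-Co2 shares 47.1% of words, against 5.22, 0.265, 0 and 0% for these genes. mt-Co1 also shares 47.1% there, but 29.6% with chromosome 1, and stood at 519 TPM. No biological explanation was tested.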

How the results depend on the processing

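The rescaling over protein-coding genes was chosen after seeing the data, as were the tests on protein-coding genes alone and on counts of the second transcript table; the cause of the changes below was not tested unless the alternative itself states it. The common biological coefficient of variation stayed within its error under all 11 alternatives. That error was computed from the fits without a replicate, so those fits could hardly fall outside it. For DESeq2 the value compared was another measure, the square root of the median fitted dispersion (0.150). No gene pair changed sign, but 12 of their values moved beyond the replicate SD, among them Il12b over Il12a (3.56 with a pseudocount of 1) and Cxcl10 over Cxcl9 (6.51 on expected counts). Of these moves 8 were on expected counts, 2 with the pseudocount and 2 in the second transcript table. FPKM keeps the TPM ratios, and leaving out a replicate cannot move a mean beyond that SD, so these alternatives were no check of the pairs. Median list levels moved beyond the replicate SD in 135 cases and stayed within it in 167, with the median of small structured RNAs at 1.80 with TMM-scaled CPM and 13.03 over detected members against 6.01. Of the 167, 28, 27 and 28 came from leaving out replicate 1, 2 and 3, a weak check because the SD comes from the same libraries. Fewer genes (5722) were detected at 5 TPM. At 5 TPM the detected members were 4 of alternative activation, 4 of cell cycle, 4 histones, 1 neutrophil, 1 dendritic cell, 1 T and NK cell, 0 B cell and 0 stromal marker. At 10 expected counts they were 19 cell cycle genes, 8 nuclear long noncoding RNAs, 15 histones, 5 neutrophil, 6 dendritic cell, 2 B cell and 3 stromal markers and 1 sex-linked gene. Cell cycle members numbered 15 at 0.5 TPM, 14 with FPKM and 17 rescaled over protein-coding genes, which gave 2 stromal markers, and the second transcript table gave 1 dendritic cell and 0 B cell markers. The cytokine minus inhibitor difference reversed to 1.24 over detected members alone. Interferon response minus cytokines was 4.06 with TMM-scaled CPM and 0.90 over detected members. Macrophage identity minus alternative activation was 9.34 and 5.48 with pseudocounts 0.1 and 5, 8.07 with FPKM, 6.85 in the second table, 8.77 rescaled over protein-coding genes, 8.37 with TMM-scaled CPM and 3.31 over detected members. Housekeeping minus nuclear long noncoding RNAs was 8.71 and 5.25 with pseudocounts 0.1 and 5, 7.66 with FPKM, 6.40 in the second table, 7.88 with TMM-scaled CPM and 3.76 over detected members. Leaving out a replicate gave 82 to 119 variable genes, where fewer samples were tested, and DESeq2 gave 59. The leading transcript was the same in every library for 95 to 96.1% of genes without a replicate and for 92.7% in the second table, and in both tables for 86.4% at a mean of 50 TPM or more and 85.4 to 86.6% without a replicate. Shares of the leading transcript of single genes moved beyond the replicate SD for 11 of 19 genes in the second table. Genes over 2-fold apart between the tables numbered 1101 and 99 with pseudocounts 0.1 and 10, and 107 rescaled over protein-coding genes.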

Other observations

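No tests were made in this part, and the genes were chosen after their values were seen. Several long noncoding RNA genes outside the fixed lists were abundant in the cytosolic fraction. AW112010, an interferon-inducible transcript (chromosome 19, 11047612 to 11055808), stood at 374 ± 113 TPM (SD, n = 3) and at 195 TPM in the second transcript table. 2900097C17Rik (60.2 ± 3.25), the small nucleolar RNA host genes Gas5 (40.3 ± 3.28) and Zfas1 (32.8 ± 8.45), and Gm20559 (37.6 ± 10.1) followed. Gm10076 (350.1 ± 53.3) and Gm26716 (115 ± 10.8) were as abundant in the gene table, but stood at 0.456 and 0.0544 TPM in the second transcript table and are uncertain.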
